A study of Ovis aries with 2 samples.

How the data were processed

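Single cells of a sheep carotid artery and of an implanted acellular vascular graft were profiled by droplet-based single-cell RNA sequencing, with 1 library of each, both taken out 12 weeks after implantation per the labels. The labels set a target of about 10000 cells per capture. One title names the native sample an aorta, while its source and description name the carotid artery, and it is called the native artery here. The graft sample is titled H2R5-ATEV. The labels do not say how many animals gave the tissue. Cells were released by enzymatic digestion from the inside of the clamped vessel, per the labels' protocols, so cells near the lumen had the most contact with the enzymes.

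The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger 7.2.0 per the file headers, as a filtered matrix for each library. The submitters' processing notes also name bcl2fastq 2.20.0.422, R 4.3.3 and Seurat 5.0.0 without a role. The genome build was not given in the sources used here, and no coordinates are printed. The matrices list 21890 genes, of which 6435 have no symbol. Genes without a symbol held 22.7% of the native and 18.8% of the graft UMIs, and none of them could be named, because the reference table of gene names carried no matching identifiers.

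The native library held 11371 barcodes and 43183715 UMIs, with a median of 1366 UMIs and 788 genes per barcode. The graft library held 1229 barcodes and 36238351 UMIs, with a median of 17050 UMIs and 4299 genes. Barcodes with fewer than 200 genes or more than 20% UMIs from the 13 mitochondrial genes were removed, which took out 266 native and 143 graft barcodes. Scrublet, run in scanpy 1.11.5, marked 1 native barcode (0.00879%) and 3 graft barcodes (0.244%) at its automatic threshold, too few to be a working call. The highest Scrublet scores were therefore removed at 0.8% of barcodes per 1000 barcodes, as fixed before the data were examined, which meant 1034 native and 12 graft barcodes. After these steps 10080 native and 1074 graft barcodes were kept, with medians of 1508 and 20737.5 UMIs. Some native barcodes fell under both removals, since 11105 passed the gene and mitochondrial limits alone.

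Kept cells of both libraries were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1. A cluster was named after the marker list with the highest mean score, using marker lists fixed before the data were examined. It stayed unnamed with fewer than 3 markers at least 2-fold above the other clusters, with more than 50% as many markers of another class, with more markers of another class among its 10 leading genes, or when shallow with no marker there. These naming limits were set after the clusters had been seen, so the share of unnamed cells is given for each library. Class names stand for cells with the markers of that type, such as endothelial-like cells.

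Within each class with at least 30 cells in both libraries, UMIs were summed per library and scaled to a total of 1000000 per class and library (CPM). CPM carry exact Poisson intervals, ratios carry exact conditional binomial intervals, and shares of cells carry exact Clopper-Pearson intervals, all at 95%. Intervals cover counting error only. Where a library held 0 UMIs of a gene, folds were taken against a floor of 3 counts in that library, which is a convention and not a 95% bound. Named genes were chosen by a fixed rule: the 12 with the highest and the 12 with the lowest log2 ratio after adding 5 CPM, among genes with a symbol, at least 50 CPM and at least 30 UMIs in the higher library. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes were left out, and so were genes whose CPM in the class lay below the CPM of all other cells divided by 4, against free RNA. A result this rule selects in endothelial cells is not reported here. Members named to describe a gene list are among its 4 with the highest mean CPM.

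Over a gene list, the median log2 ratio (with the same 5 CPM added) of members with at least 10 UMIs is given with an exact order-statistic interval over members. Its percentile among 10000 random lists of the same size, matched on mean expression, describes these 2 libraries. To compare shares of cells with marker transcripts at equal depth, each cell was thinned to 1000 UMIs and counted at 2 or more UMIs of the list. Thinning left out 3774 native and 162 graft cells. With 1 library per group no test between the groups was made, and no difference has a replicate check.

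The gene tables were tested on simulated counts drawn from the mean profile and summed UMIs of each class, with 200 genes changed by known folds. The changed genes were drawn from those of at least 50 CPM, so recovery at lower levels was not tested. Free RNA and differences in clusters between the libraries were not simulated. Within 0.5 log2 units, 50 of 50 genes made 2-fold higher and 48 of 50 made 4-fold lower were recovered in the endothelial simulation over 18872 genes. In the T or NK simulation over 17049 genes, the counts were 50 of 50 and 40 of 50. With no gene changed, 22 of 23 lists in the endothelial simulation lay between percentiles 2.5 and 97.5.

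Alternatives covered the mitochondrial limit (10% or none), at least 500 genes per cell, doublet removal, clustering resolution (0.5 and 2), 4000 variable genes, separate clustering, equal cell numbers and classes from each cell's own markers. For lists they also covered thinning, equal weight per cell, other scalings and other minimums of 30 and 1 UMIs. For shares of cells with marker transcripts they covered thinning to 2000 UMIs and a minimum of 3 UMIs. Settings chosen after seeing the data were cells of at least 5000 UMIs, every cluster at its best-scoring class, and smooth muscle cells without those that carried macrophage markers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9 were used.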

Results

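Single-cell transcriptomes were measured in 1 library from the native carotid artery of sheep and 1 library from a cell-free tissue-engineered vascular graft explanted after 12 weeks. The labels title the graft sample H2R5-ATEV. The graft holds no cells when implanted, so the design asks which cells had populated it and how they differ from those of the artery. After filtering, 10080 native cells with 40602114 UMIs and 1074 graft cells with 35167561 UMIs were compared. Depth differed strongly, with medians of 1508 UMIs per native cell and 20737.5 UMIs per graft cell. No replicate library exists for either tissue, so every difference below describes these 2 libraries.

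The graft held endothelial-like, smooth muscle-like and macrophage-like cells, named here without the ending, with higher shares of macrophages and smooth muscle cells than the artery and lower shares of endothelial cells and fibroblasts. Macrophages, with C1QA, C1QB, AIF1 and CTSS raised in each of their clusters, made up 29.7% of graft cells (319 cells, 95% interval 27.0 to 32.5%) and 12.96% of native cells (1306 cells, 12.3 to 13.6%). Smooth muscle cells, with MYH11, ACTA2, TAGLN and CNN1, made up 18.7% of graft cells (201 cells, 16.4 to 21.2%) and 1.42% of native cells (143 cells, 1.20 to 1.67%). Endothelial cells, with ESAM, PLVAP and VWF each raised in most of their clusters, made up 19.6% of graft cells (210 cells, 17.2 to 22.1%) and 46.7% of native cells (4709 cells, 45.7 to 47.7%). Fibroblasts, with DCN, PI16, MFAP5 and SFRP2, were at 2.61% in the graft (28 cells) and 21.7% in the artery (2189 cells), and with 28 graft cells their expression was not compared.

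T or NK cells made up 6.42% of graft cells (69 cells) and 11.4% of native cells (1148 cells). B or plasma cells were at 1.30% in the graft (14 cells) and 0.327% in the artery (33 cells). Unnamed clusters held 21.7% of graft cells and 5.48% of native cells. Most unnamed graft barcodes, 17.97% of all kept graft cells, belonged to 1 cluster with a median of 651 UMIs.

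Among cells of at least 5000 UMIs, the differences had the same directions in 4 classes: macrophages were at 39.5% of graft and 15.5% of native cells, smooth muscle cells at 25.3% and 1.76%, endothelial cells at 23.4% and 45.1%, and fibroblasts at 3.07% and 20.8%. The depth gap and the digestion from the lumen can set these shares. With each library clustered by itself the macrophage difference was -1.12 points and the T or NK difference 1.27 points, against 16.7 and -4.96 points. The endothelial difference of -27.2 points was -5.51 at a mitochondrial limit of 10%, -5.65 at resolution 0.5 and -4.08 with 4000 variable genes. In these runs 2317, 2494 and 2307 native cells were named endothelial, against 4709, with 9599, 10080 and 10080 native cells kept. The graft class held 193, 205 and 202 cells, so the change lies mostly in which native cells were named endothelial.

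**Figure D1:**
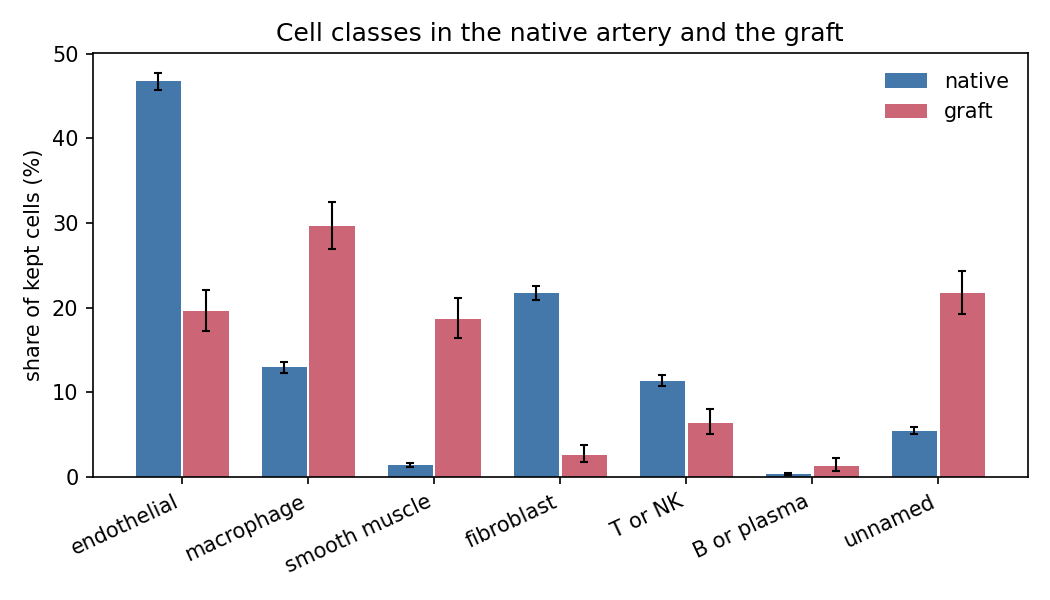
Share of kept cells (%) in each class for the native artery (10080 cells) and the graft (1074 cells), with exact 95% binomial intervals as error bars. Macrophages stand at 12.96% and 29.7%, and endothelial cells at 46.7% and 19.6%.

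Graft smooth muscle cells carried contractile transcripts at about the level of the artery and more matrix and matrix-degrading transcripts. Most members of the contractile list are also markers that named the class. Clusters low in them would not enter it, so the similar contractile level follows in part from the naming. COL1A1, a chain of fibrillar type I collagen, was 6.19-fold higher in the graft class (5.88 to 6.53), at 11337 against 1830 CPM. FN1, which encodes fibronectin, was 3.47-fold higher (3.29 to 3.67). MMP13 (ENSOARG00020029769), a collagenase, stood at 1295 CPM in the graft with 0 native UMIs. It was 348-fold higher against the floor of 3 counts, and the exact interval of its ratio starts at 283-fold. The native class summed to 806492 UMIs and the graft class to 10873023 UMIs. Fibroblast markers were also higher, with means of 29.8 UMIs per graft and 8.53 per native smooth muscle cell after thinning to 1000 UMIs, and 5 of them were at least 2-fold up in cluster 13, the main graft cluster of the class.

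Of 19 measured members of the fibrillar collagen and matrix list, 12 were at least 2-fold higher and 0 at least 2-fold lower in graft smooth muscle cells, with a median log2 ratio of 1.63 (0.36 to 2.63, percentile 100). COL1A2 was 3.11-fold and COL3A1 2.18-fold higher. The contractile list had a median of 0.33 (0.05 to 0.60, percentile 95.8), with 2 of 20 members at least 2-fold higher and 2 lower. Its most abundant members were CALD1 (1.50-fold higher), ACTA2 (1.44-fold), TAGLN (1.76-fold) and TPM1 (1.79-fold). The modulated smooth muscle list had a median of 0.88 (0.16 to 1.79, percentile 99.97), with TIMP1, an inhibitor of metalloproteinases, 3.18-fold higher and VIM 1.12-fold higher. MGP, an inhibitor of calcification, was at 9539 CPM in the graft and 17525 CPM in the artery. The elastic fibre list had a median of 0.14 (-0.73 to 0.89, percentile 79.3), with ELN at 2639 and 2398 CPM and MFAP4 at 84.98 and 586 CPM in graft and artery.

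Matrix proteolysis genes had a median of 1.58 in the same class (0.16 to 2.96, percentile 100), with 11 of 18 members at least 2-fold higher. The metalloproteinase genes MMP9, MMP12 and MMP1 had 0 native UMIs and were 83.5-fold, 70.1-fold and 41.5-fold higher against the floor. Their exact intervals start at 67.9-fold, 56.9-fold and 33.7-fold. MMP9 also stood at 459 CPM in the other graft cells, above its 311 CPM in the smooth muscle class. Without the graft smooth muscle cells that carried macrophage markers, a setting chosen after seeing the data, the log2 ratios were 8.06 for MMP13 and 5.94 for MMP9, against 8.02 and 5.98, and the proteolysis median was 1.45. Other genes among the 12 highest were ANKRD1 (67.3-fold higher, 37.6 to 135), THBS1 (37.998-fold, 26.8 to 55.9), TMEM132D (66.8-fold), COL12A1 (42.7-fold) and NLGN1 (27.4-fold). GRIP1, RARRES1 and NRG3 each rested on 1 native UMI, with GRIP1 at 229-fold and an interval from 41.01 to 9035, and RARRES1 was higher in the other graft cells (639 CPM) than in this class (195 CPM).

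The genes lowest in the graft class included OGN, which encodes the proteoglycan osteoglycin, 150-fold lower (115 to 200), and LAMA2, a laminin chain, 119-fold lower (86.3 to 169). WIF1, a secreted WNT inhibitor, was 70.04-fold lower and ITGA8, an integrin chain of contractile smooth muscle, 24.1-fold lower. MDGA2 (62.7-fold), C1QTNF7 (55.0-fold), ZBTB16 (49.1-fold), HPGD (47.5-fold), AOX1 (42.0-fold), PDZRN4 (30.2-fold), COL21A1 (20.9-fold) and IGFBP3 (20.2-fold) were also lower. Cluster 13 held 197 of the 201 graft cells and cluster 17 held 131 of the 143 native cells, so the class compares different clusters, and a cluster mostly of 1 library may be that library rather than a type. With the class taken from each cell's own markers, the contractile median was 1.16.

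Graft macrophages carried far more transcripts of lipid handling and lysosomes than native macrophages. SPP1 (ENSOARG00020024091), which encodes osteopontin, was at 2763 CPM in the graft and 0.802 CPM (6 UMIs) in the artery. GPNMB, a glycoprotein of lipid-laden macrophages, was 259-fold higher (141 to 541), and TREM2, a lipid-sensing receptor, 40.4-fold higher (30.8 to 54.0). CD74, the invariant chain of MHC class II, was at 4282 CPM in the graft and 11413 CPM in the artery.

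Of 18 measured members of the lipid and lysosome list, 16 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.88 (1.41 to 4.67, percentile 100). The median was 1.54 with each library clustered by itself and 1.46 with native cells subsampled to the graft number. In those runs the graft class held 190 and 153 cells in place of 319. They thus also change which graft cells are compared, here and for the lists below. CTSB was 3.15-fold, PSAP 2.38-fold and FABP5 9.58-fold higher. Of 8 measured MHC class II members, 6 were at least 2-fold lower, with a median of -1.31 (-1.76 to 0.82, percentile 0). The classical class II chains of the list, such as HLA-DRA, had no matching symbol. The measured members are CD74, CIITA, the HLA-DM and HLA-DO genes, CTSS and IFI30. This MHC class II median was 0.56 with native cells subsampled, -0.61 with separate clustering and -0.58 after thinning to 1000 UMIs, so its direction stays open. HLA-DMB was at 310 and 651 CPM in graft and artery, whereas CTSS was 1.24-fold and IFI30 1.77-fold higher in the graft. The pro-inflammatory list had a median of -0.48 (-0.83 to 0.37, percentile 0.19), with CXCL8 at 2036 and 3626 CPM and NFKBIA at 2155 and 3441 CPM in graft and artery. With equal weight for each cell the pro-inflammatory median was 0.46, and after thinning 0.16. The reparative list had a median of 0.22 (-0.31 to 1.62, percentile 85.7), with 5 of 16 members at least 2-fold higher, among them FOLR2 (6.34-fold) and CD163 (2.18-fold), while CSF1R was at 331 and 437 CPM. The reparative median was 1.02 with equal weight for each cell. An unnamed cluster with macrophage markers, led by the list members LYVE1 and F13A1, held 53 native cells and 1 graft cell. It lay outside the class, so its reparative transcripts do not enter the native side.

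Other genes highest in graft macrophages were APOE (70.7-fold, with 1001 CPM in the other graft cells above its 670 CPM in macrophages), LPL, a lipase (30.8-fold, 26.5 to 35.9), S100A12 (54.9-fold), S100A8 (56.8-fold) and the lysosomal channel gene MCOLN3 (190-fold). FABP4, a fatty acid carrier, stood at 206 CPM with 1 native UMI, and the elastase gene MMP12 at 166 CPM with 1 native UMI. PDPN and MMP9 had 0 native UMIs and were 416-fold and 357-fold higher against the floor, with exact intervals from 338-fold and 290-fold. MMP9 was, however, higher in the other graft cells (556 CPM) than in macrophages (143 CPM). The genes lowest in the graft were CST3, the protease inhibitor cystatin C (7.63-fold lower, 7.50 to 7.77), GPR141 (12.7-fold), CTNND2 (10.5-fold), PTGS2 (7.96-fold), the chemokine receptor gene CCR2 (7.35-fold, 5.80 to 9.39), Ovar-DRA (5.99-fold), GPM6A (5.45-fold), RGS18 (5.41-fold), FGL2 (5.13-fold), CLEC5A (4.95-fold), PLAC1 (4.79-fold) and AIG1 (4.50-fold). PTGS2, FGL2 and PLAC1 were higher in the other native cells (367, 586 and 194 CPM) than in native macrophages (177, 205 and 171 CPM). Cluster 12 held 261 of the 319 graft macrophages and 1 native cell, while clusters 5 and 10 held most of the native ones. With native cells subsampled to the graft number, log2 ratios changed sign for LPL (-0.74), CCR2 (0.70) and GPM6A (0.28). In that run the macrophage class held 153 graft and 65 native cells, against 319 and 1306, so its graft side differs too.

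**Figure D2:**
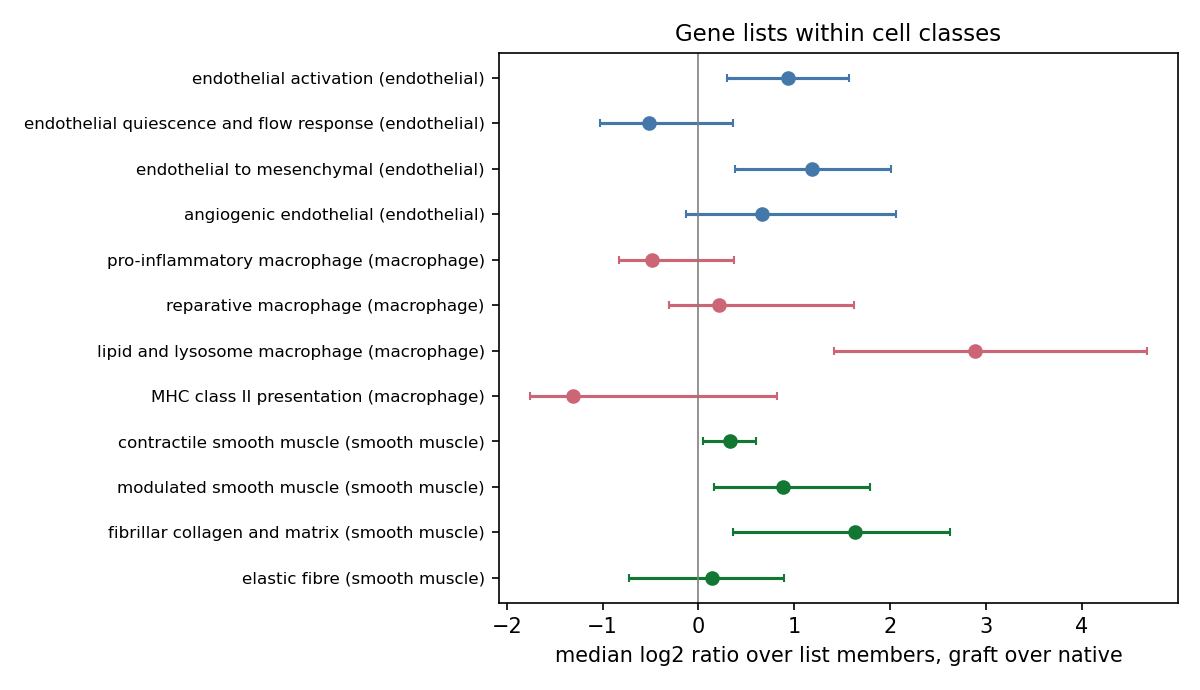
Median log2 ratio of graft over native CPM across the members of 12 gene lists (horizontal axis), each in the class named in parentheses, with exact order-statistic 95% intervals over members. The lipid and lysosome list in macrophages is highest at 2.88 and the MHC class II list in macrophages lowest at -1.31, a median that was 0.56 with native cells subsampled.

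Graft endothelial cells carried more transcripts of the cell cycle and endothelial to mesenchymal lists, and fewer of GJA5 and CD74. ANKRD1 (ENSOARG00020010048), a target of mechanical and YAP signalling, was at 1934 CPM in the graft and 1.43 CPM in the artery. GJA5, an arterial gap junction gene, was at 122 CPM in the graft and 710 CPM in the artery. CD74 was 31.4-fold lower in the graft (28.6 to 34.4), but the other native cells, at 4124 CPM, lay above the 1479 CPM of native endothelial cells, so free RNA may add to its native level.

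The endothelial activation list had a median log2 ratio of 0.94 (0.30 to 1.57, percentile 99.98), with 7 of 14 members at least 2-fold higher and 1 lower. After thinning to 1000 UMIs it was 0.84 (-0.62 to 1.20). The adhesion gene SELP was 2.57-fold and NFKBIA 2.92-fold higher, and VWF was 1.23-fold higher. In the endothelial to mesenchymal list 10 of 19 members were at least 2-fold higher and 2 lower, with a median of 1.19 (0.38 to 2.01, percentile 100), which was 0.46 with equal weight for each cell. VIM was 1.79-fold, FN1 2.28-fold and S100A4 15.5-fold higher. The angiogenic list had a median of 0.67 (-0.13 to 2.06, percentile 99.96), with COL4A1 38.1-fold, NRP1 4.48-fold, PLVAP 1.57-fold and FLT1 1.17-fold higher. COL4A1 was at 893 CPM in graft endothelial cells and 1715 CPM in the other graft cells. The quiescence and flow response list had a median of -0.51 (-1.03 to 0.36, percentile 0.19), with 6 of 20 members at least 2-fold lower and 3 higher. Of its abundant members, TEK was at 372 and 624 CPM and BMX at 149 and 686 CPM in graft and artery, while NOS3, the endothelial nitric oxide synthase gene, was 1.57-fold higher.

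Cell cycle genes had a median of 1.84 in endothelial cells (1.11 to 2.85, percentile 100), with 12 of 14 members at least 2-fold higher, such as TOP2A (23.3-fold), CENPF (71.5-fold), STMN1 (6.70-fold) and TPX2 (4.52-fold). Cluster 18, with TOP2A and CENPF among its leading genes, was named macrophage as a whole, so cycling cells of other classes may lie there. The hypoxia and glycolysis list had a median of 0.99 (0.37 to 1.55), with GAPDH 2.99-fold, ENO1 3.43-fold, PKM 3.18-fold and ALDOA 2.07-fold higher. The hypoxia median was 0.52 after thinning to 1000 UMIs. The complement list had a median of -1.29 (-2.17 to 0.01), with CD59 at 361 and 415 CPM, C1R at 47.2 and 230, C1S at 9.51 and 92.8 and C1QA at 21.6 and 73.7 in graft and artery, and the complement median was -0.70 after thinning. Other genes highest in the graft were IGFBP5 (94.6-fold), RGS7 (94.0-fold), COL12A1 (84.2-fold), MYO10 (303-fold), NPPC, which encodes C-type natriuretic peptide (131-fold), FAM171B (141-fold), TFPI, a coagulation inhibitor (60.6-fold), MUSTN1 (32.4-fold) and the oxidised LDL receptor gene OLR1 (26.8-fold, 25.2 to 28.5). The lowest were CCSER1 (43.6-fold lower), FGL2 (33.6-fold), B3GALT1 (87.9-fold), UNC5C (32.4-fold), the caveolar gene CAVIN2 (20.6-fold, 18.1 to 23.5), KIF26B (24.4-fold), NCAM1 (21.1-fold), ZBTB16 (87.4-fold), CDKN1C, a cell cycle inhibitor (24.3-fold), DKK3 (17.8-fold) and BEX5, with 2 graft UMIs (363-fold, 100.3 to 3002). FGL2 and ZBTB16 were higher in the other native cells (593 and 106 CPM) than in native endothelial cells (414 and 88.5 CPM). Cluster 15 held 176 of the 210 graft cells, while clusters 0, 2, 3 and 4 held nearly all native ones. Without the added 5 CPM for any member, and with counts under 3 set to the floor of 3, the angiogenic median was 1.07. The complement median was then -1.77 and the cell cycle median 2.65.

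T or NK cells of the graft carried fewer interferon gamma transcripts. IFNG was 10.8-fold lower (5.66 to 23.7), at 19.1 CPM from 9 UMIs in the graft and 206 CPM in the artery. Cluster 7, with IFNG among its leading genes, held 582 of the 1148 native T or NK cells and 2 of the 69 graft ones, so the class compares different clusters and the contrast may follow which of them each library holds. MX2, an interferon-induced antiviral gene, was 12.3-fold higher (7.97 to 19.2) and ISG15 6.65-fold higher (4.39 to 9.99), both at levels near those of the other graft cells (57.9 and 71.5 CPM against 108 and 91.4 CPM). The interferon response list had a median of 0.53 (0.23 to 1.16, percentile 99.98), with 3 of 14 members at least 2-fold higher; IFI6 was 1.97-fold higher. After thinning to 1000 UMIs the interferon median was 0.41 with an interval that spans 0 (-1.41 to 0.69). The cytotoxic and T cell activation list had a median of 0.87 (-0.20 to 1.40, percentile 100), with 7 of 17 members at least 2-fold higher and 1 lower. Its most abundant members were within 2-fold, with CTSW at 548 and 673 CPM, KLRK1 at 525 and 603, NKG7 at 308 and 372 and CD69 at 287 and 391 in graft and artery. After thinning the cytotoxic median was 0.27 (-0.08 to 0.91).

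Other genes higher in graft T or NK cells were ABCA1 (7.31-fold), RHEX (6.03-fold), BLK (5.92-fold), CA8 (6.25-fold), RNF212B (5.61-fold), CDK14 (4.92-fold), PPARG (5.36-fold), GLIS3 (5.36-fold), TIAM1 (5.80-fold) and HVCN1 (5.00-fold). ABCA1 and GLIS3 were higher in the other graft cells (307 and 143 CPM) than in graft T or NK cells (117 and 106 CPM). The sterol synthesis genes HMGCS1 (3.93-fold), CYP51A1 (3.41-fold) and MSMO1 (3.26-fold) were lower, and so were PHGDH (3.79-fold), BAMBI (3.65-fold), NR4A1 (3.51-fold), CTBP1 (3.48-fold), WDR47 (3.48-fold), EEF1A1 (3.33-fold), HSPB1 (2.95-fold) and HSPA6 (2.73-fold). HSPB1, NR4A1 and WDR47 were higher in the other native cells (1151, 421 and 54.4 CPM) than in native T or NK cells (319, 127 and 51.8 CPM). The graft class held 69 cells and 470695 UMIs. HSPB1 changed sign when each library was clustered by itself (0.78 on the log2 scale).

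At equal depth, macrophage transcripts were found in a larger share of graft smooth muscle cells than of graft endothelial cells. After thinning to 1000 UMIs, 19.9% of graft smooth muscle cells (40 of 201, 14.6 to 26.1%) had 2 or more macrophage marker UMIs, against 0.917% of native smooth muscle cells (1 of 109, 0.0232 to 5.01%). The background in the graft was 1.99% in endothelial cells (4 of 201, 0.545 to 5.02%) and 1.47% in T or NK cells (1 of 68, 0.0372 to 7.92%). At 2000 UMIs the T or NK share was 15.4% (7.63 to 26.5%), which overlaps the 28.4% of smooth muscle cells (22.2 to 35.1%). Median depths before thinning were 34653 UMIs in graft smooth muscle, 34266 in graft endothelial and 6425.5 in graft T or NK cells, and the unthinned shares were 93.5%, 79.5% and 56.5%. In the reverse direction, 3.15% of graft macrophages (10 of 317) and 7.69% of native macrophages (57 of 741) had 2 or more UMIs of smooth muscle markers. The T or NK cells of the same libraries were at 7.35% in the graft (2.43 to 16.3%) and 4.83% in the artery (3.39 to 6.66%), with intervals that overlap those of macrophages (1.52 to 5.72% and 5.88 to 9.85%), and the macrophage shares are read as background. Endothelial markers were found in 11.04% of graft macrophages (7.81 to 15.02%) and 6.97% of graft smooth muscle cells (3.86 to 11.4%), with overlapping intervals, and in 24.4% of native macrophages.

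Cell cycle transcripts were found in a larger share of graft than of native endothelial cells. At 1000 UMIs, 7.46% of graft endothelial cells (15 of 201, 4.24 to 12.0%) and 0.891% of native ones (29 of 3253, 0.598 to 1.28%) had 2 or more UMIs of the cell cycle list, against 70% and 9.07% before thinning, and 9 graft and 1456 native endothelial cells were too shallow to enter. Smooth muscle cells were at 4.48% in the graft (9 of 201, 2.07 to 8.33%) and 0.917% in the artery (1 of 109). Macrophages were at 8.83% and 9.31%, within each other's intervals, and T or NK cells at 7.35% and 14.1% in graft and artery. The intervals of the 4 graft classes overlapped, so a contribution of free RNA to these shares stays open. Cluster 18, with TOP2A, UBE2C and CENPF among its leading genes, held 94 native and 17 graft cells and was named macrophage as a whole. Cycling cells of other classes may lie in it, so it can raise the macrophage shares and lower the others, which was not tested.

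**Figure D3:**
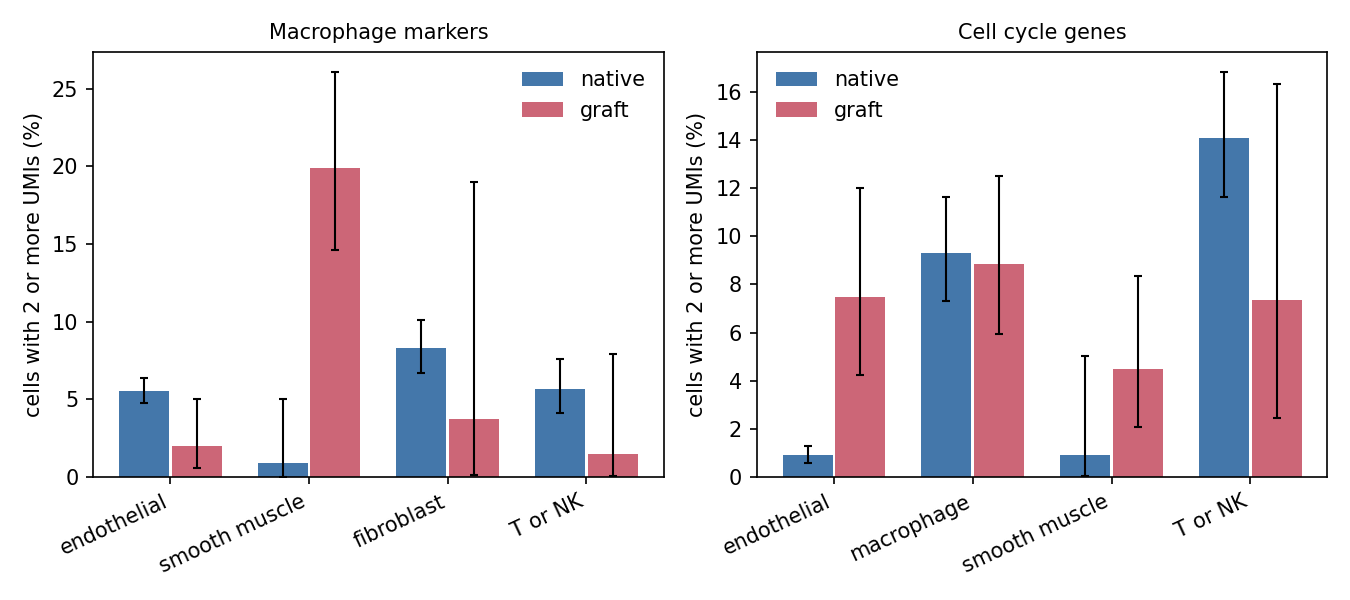
Share of cells (%) with 2 or more UMIs of the macrophage marker list (left) or the cell cycle list (right) after thinning each cell to 1000 UMIs, by class and library, with exact 95% binomial intervals. Graft smooth muscle cells stand at 19.9% for macrophage markers, and graft endothelial cells at 7.46% for cell cycle genes.

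Summed over all kept cells, with no cell classes, the graft library was higher in the contractile (median log2 ratio 1.74, 1.24 to 2.81), matrix proteolysis (1.90, 0.66 to 2.51) and lipid and lysosome lists (2.12, 1.06 to 3.66). SPP1 was 602-fold higher (497 to 736), the contractile gene ACTA2 21.4-fold (20.6 to 22.3) and ACP5, which encodes an acid phosphatase of osteoclasts and macrophages, 33.6-fold (31.4 to 35.9). Of the 25110 graft UMIs of ACP5, 18611 lay in the unnamed graft cluster. Its 12 graft barcodes of at least 5000 UMIs held 46756 UMIs of ACP5, CTSK and MMP9 together, and 1 barcode held 23830 of them. The sums of ACP5 and MMP9 thus rest in large part on few barcodes. MMP13 and MMP9 had 0 UMIs in the whole native library, where the exact interval reaches 0.0909 CPM. They stood at 430 and 413 CPM in the graft. ACTG2 (151-fold), TMEM132D (188-fold), THBS1 (59.0-fold), S100A12 (69.5-fold), COL4A1 (31.7-fold) and ANKRD1 (792-fold) were also higher. KERA, a keratan sulfate proteoglycan of stromal cells, was 75.6-fold lower (64.1 to 89.8), CHRDL1 39.8-fold, ITGBL1 36.5-fold, NTRK2 26.0-fold, ADAMTSL3 25.8-fold, CCL26 23.0-fold, PCOLCE2 20.3-fold, OGN 19.9-fold and PTGDS 17.0-fold lower. These sums follow the cell classes as well as expression within them.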

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

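The setting without marker-bearing cells and the tests of the cluster below were chosen after the values had been seen; the other alternative runs in this part were planned. The MHC class II list went opposite ways in endothelial cells (median log2 ratio -1.82) and smooth muscle cells (1.26). After thinning to 1000 UMIs these medians were -1.10 (-4.23 to 0.45) and 0.27 (0 to 2.58), and both intervals reach 0. The hypoxia and glycolysis list was higher in graft endothelial (0.99), macrophage (0.50) and smooth muscle cells (0.93) and lower in T or NK cells (-0.39). With native cells subsampled the macrophage median was -0.061, which turns its direction, and after thinning the endothelial one was 0.52. The subsampled run named 153 graft cells macrophages in place of 319. The interferon response list was lower in endothelial cells (-0.85) and higher in smooth muscle (0.61) and T or NK cells (0.53). With classes from each cell's own markers the smooth muscle median was -0.086, which turns its direction, and after thinning the T or NK interval spans 0 (-1.41 to 0.69). These differences between cell classes were not tested.

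Without the smooth muscle cells that carried macrophage markers, the MHC class II median in smooth muscle was 0.41 and the interferon median 0.29. The lipid and lysosome median there was 0.70 in place of 1.55.

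A cluster led by ACP5, MMP9, CTSK, ATP6V0D2 and ITGB3, genes known from osteoclasts, held 17.97% of kept graft barcodes (193) and 0.0893% of native ones (9), and it enters the sums over whole libraries and over other graft cells but no comparison within a class. In its 12 graft barcodes of at least 5000 UMIs the median was 644.5 UMIs of ACP5, CTSK and MMP9 together, with a range of 0 to 23830. The mean in graft endothelial cells was 2.19. These genes lead the cluster, so a high level is partly its definition. Counts so far above 2.19 argue against free RNA only in the barcodes that hold them. Barcodes of at least 5000 UMIs with the 3 genes at 0.5 or more of the level in the shallow barcodes (3846 CPM) numbered 65. Of these, 8 lay in the cluster and 53 were named macrophages. Graft macrophages as a class stood at 1744 CPM of the 3 genes, with CTSK alone at 1221 CPM. The 53 can therefore pass on CTSK, and the signal in deep barcodes rests on the 8. A single barcode held 23830 of the 46756 UMIs in the 12. The 149 barcodes under 1000 UMIs held 2.48 UMIs each (2.24 to 2.75), which overlaps graft endothelial cells (1.99 to 2.40) and lies above T or NK cells (0.64 to 1.09). Other graft barcodes under 1000 UMIs held 0.154 each (2 UMIs in 13 barcodes, 0.0186 to 0.556), but the cluster was picked for these genes and those barcodes lie outside it, so free RNA and small or broken cells cannot be told apart in them. Osteoclast-like cells in the graft may account for the deep barcodes, as a hypothesis that the graft group allows and no further test addressed.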

How the results depend on the processing

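Chosen after seeing the data were the settings with cells of at least 5000 UMIs, with every cluster at its best-scoring class, and without smooth muscle cells that carry macrophage markers. No paired analysis was possible because each group is 1 library and no result comes from a test. The endothelial, fibroblast and smooth muscle share differences kept their sign in each alternative run, while the macrophage and T or NK differences did not. The cause of these sign changes was not tested. The endothelial values of -5.51, -5.65 and -4.08 below came with fewer native cells named endothelial (2317, 2494 and 2307 against 4709). The endothelial difference (-27.2 points) was -5.51 at a mitochondrial limit of 10%, -24.0 with none, -21.9 with no doublets removed, -22.0 at Scrublet's automatic threshold, -5.65 at resolution 0.5, -4.08 with 4000 variable genes, -30.3 with separate clustering, -32.9 with native cells subsampled, -13.1 with classes from each cell's own markers, -31.9 at the best-scoring class and -21.7 for cells of at least 5000 UMIs. The fibroblast difference (-19.1) was -14.7 with no mitochondrial limit, -17.3 at 500 genes, -15.5 with no doublets removed, -15.9 at the automatic threshold, -28.6 and -8.44 at resolutions 0.5 and 2, -15.7 with 4000 variable genes, -11.8 with separate clustering, -2.79 with native cells subsampled, -17.1 from own markers and -17.7 at 5000 UMIs. The macrophage difference (16.7) was 10.7 with no mitochondrial limit, 23.02 at 500 genes, 25.2 with no doublets removed, 23.5 at resolution 2, -1.12 with separate clustering, 8.19 with native cells subsampled, 34.2 at the best-scoring class and 24.03 at 5000 UMIs. The smooth muscle difference (17.3) was 12.8 at 500 genes, 9.75 at resolution 2, 8.28 with separate clustering, 8.29 with native cells subsampled, 12.3 from own markers, 14.2 without cells that carry macrophage markers and 23.6 at 5000 UMIs. The T or NK difference (-4.96) was 1.27 with separate clustering, 0.559 with native cells subsampled and -8.99 at 5000 UMIs. Of the 12 list medians led with, the contractile median in smooth muscle (0.33) was 1.16 with classes from own markers, and the pro-inflammatory median in macrophages (-0.48) was 0.46 with equal weight per cell. Every other value of these lists lay within the main interval, which for some lists spans 0. Inside it the MHC class II median in macrophages (-1.31) was 0.56 with native cells subsampled, -0.61 with separate clustering and -0.58 after thinning, and the pro-inflammatory median was 0.16 after thinning. The lipid and lysosome median in macrophages (2.88) was 1.54 with separate clustering and 1.46 with native cells subsampled. The macrophage class held 190 and 153 graft cells in those 2 runs, against 319 in the main one. With equal weight per cell the reparative median (0.22) was 1.02 and the endothelial to mesenchymal median (1.19) was 0.46. Fibroblast lists, and smooth muscle lists with native cells subsampled (10 native cells), gave no value. Thinned to 2000 UMIs, macrophage markers were in 28.4% of graft smooth muscle (22.2 to 35.1%), 8.12% of graft endothelial (4.71 to 12.9%) and 15.4% of graft T or NK cells (10 of 65, 7.63 to 26.5%), the last overlapping smooth muscle. At that depth smooth muscle and endothelial markers were in 9.62% and 26.6% of graft macrophages, and cell cycle transcripts in 2.56% of native endothelial cells. At 3 or more UMIs the shares were 13.9% of graft smooth muscle cells, 1.26% and 4.10% of graft macrophages and 0.0615% of native endothelial cells. Among single genes and other lists, 13 values changed sign where the main interval excluded 0: with native cells subsampled CCR2 (0.70), GPM6A (0.28) and LPL (-0.74) in macrophages, HSPB1 in T or NK cells (0.45, and 0.78 with separate clustering), the elastic fibre list in T or NK cells (1.72), and the hypoxia (-0.061) and fibrillar collagen (-0.81) lists in macrophages. The fibrillar collagen list in macrophages was also -0.44 with separate clustering, -0.055 after thinning to 1000 UMIs and -0.26 with equal weight per cell, the quiescence list in macrophages was 0.25 with no doublets removed, and the interferon list in smooth muscle was -0.086 with classes from own markers. A further 578 values lay outside the interval of the main value and 3535 within it, and both counts hold sign changes where the main interval spans 0. Thinning, for example, took the fibrillar collagen list in T or NK cells from 0.30 to -0.30, the contractile list there from 0.19 to -0.22, the cell cycle list in macrophages from 0.35 to -0.10 and the MHC class II list of the whole library from -0.54 to 0.23. Scrublet's automatic threshold marked too few barcodes to serve as a doublet call. Depth limits the native side most, since 37.4% of kept native cells had under 1000 UMIs.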

Other observations

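The tests of depth, handling and free RNA in this part were chosen or split after their results had been seen, and the test for mixed droplets before. A native cluster of 478 cells with endothelial markers (PECAM1, CLDN5, TEK) was led by genes known to be induced by interferon gamma, with CXCL10 at 2804 CPM (2696 to 2916), IDO1 at 869 CPM and WARS1 at 460 CPM. It held 0 graft cells, and the deepest large native endothelial cluster had CXCL10 at 144 CPM and IDO1 at 32.3 CPM. IFNG itself was at 206 CPM in native and 19.1 CPM in graft T or NK cells, although the T or NK cluster led by XCL1, NKG7 and IFNG held 582 native and 2 graft cells, and the contrast may follow these clusters. A native cluster of 53 cells with macrophage markers was led by LYVE1 (1335 CPM) and F13A1 (2709 CPM), genes of resident perivascular macrophages, and held 1 graft cell. A cluster of 39 graft and 12 native cells had the neutrophil genes S100A8 (1791 CPM in graft cells), S100A12 (952 CPM) and CSF3R (451 CPM).

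Macrophage markers in 19.9% of graft smooth muscle cells lay above the highest upper bound in graft endothelial and T or NK cells, 7.92%; at 2000 UMIs the T or NK interval (7.63 to 26.5%) overlapped smooth muscle (22.2 to 35.1%) while the endothelial one (4.71 to 12.9%) did not, and endothelial cells of like depth argue against free RNA as the whole source. The 40 marker-bearing cells had a median of 71232.5 UMIs and the other 161 a median of 32027. Of 108 macrophage genes outside the marker list, 104 (96.3%, 90.8 to 98.98%) were raised in these cells within 2-fold of a common ratio of 23.7% of their macrophage level, as droplets holding a macrophage beside a smooth muscle cell would give. In the 40 cells MYH11, ACTA2, TAGLN and CNN1 were at 584, 4103, 3379 and 305 CPM. In the other 161 they were at 670, 4172, 3812 and 301 CPM. An admixture of 23.7% macrophage RNA would lower these genes more, so a simple mixture leaves their level unexplained. Such droplets are a candidate explanation, although doublet removal at a fixed rate took out only 12 graft barcodes. Whether such pairs formed in the tissue or at loading was not tested.

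Immediate early and heat shock genes, which respond to tissue handling, were lower in the graft, with list medians of -1.12 in endothelial (-1.51 to -0.37), -0.87 in macrophage (-1.01 to -0.58) and -0.49 in T or NK cells (-0.83 to -0.21), and -0.69 in smooth muscle with an interval that spans 0 (-1.39 to 0.25); FOS in macrophages was at 2219.6 and 4894 CPM in graft and artery. After thinning to 1000 UMIs, the highest median among endothelial, macrophage and T or NK cells was -0.57, with each interval below 0. This argues against the weight of deep cells in the sums as the source in these 3 classes, although the T or NK median was -0.033 with separate clustering. Thinning keeps the gene proportions of each cell, so it cannot address differences in cell quality that go with depth. In smooth muscle the thinned median was -0.43 with an interval to 0.20, which leaves the weight of deep cells open as well. The list median was below 0 in 4 of 4 classes, as a difference in handling would give, but handling and tissue cannot be told apart with 1 library each.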
